A study of Mus musculus with 6 samples.

How the data were processed

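The samples were 6 mouse lung RNA-seq libraries from stage E12.5, 3 labelled as ShhCre-Dnmt1 knockouts and 3 as wild-type littermates, grouped by the genotype in the labels. The authors deposited 1 table per library with an Ensembl gene identifier and a value named only as a signal, per the file headers. The submitters' processing notes name the STAR aligner, limma and the mouse build mm9, without versions, roles or order. The read counter, annotation, gene filter and scaling method are not given in the sources used here.

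The deposited values were read as log2 expression values from their range of 1 to 18.4. Raising 2 to each value gave, in every library, a whole number of reads plus an offset of 0.5, times a constant of that library. This held for 100% of the 14162 genes in each library within a tolerance of 1e-06 reads, the largest distance being 2.21e-09. The whole numbers are called reads here, and their totals are the depths given with the results. A gene without reads has a value between 1 and 1.48, depending on the library, and 2 to 19 genes per library were at 0. The lowest gene total over the 6 libraries was 60 reads, so genes below that level were not analysed here. Xist, H19 and Scgb1a1 were among the genes to be named if measured and were not analysed here.

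Gene symbols came from a table for GENCODE's GRCm38 annotation, matched by identifier, since no mm9 annotation was used here. It named 13967 of the 14162 identifiers and left 195 unnamed. The chromosome of each gene was taken from that annotation, and no positions were.

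The planned tests were fixed before the data were examined, for counts, linear or log values. Because the values were log2, limma 3.58.1 in R 4.3.3 was fitted to them without further scaling, with genotype as the only term and empirical Bayes moderation with trend and robust estimation. All genes were tested, with Benjamini-Hochberg adjustment, an adjusted p threshold of 0.05 and no fold-change limit. A fold change of a gene with few reads depends on the offset, so for the genes with the fewest reads in a group the ratio of scaled reads is given with an exact Clopper-Pearson 95% counting interval, which covers counting error only and not the spread between libraries. Dnmt1 alone also had an exact permutation test.

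The fit was tested on 5 simulated data sets of 14162 genes with the libraries' means and depths and 200 changed genes each. It recovered 72.8% of genes changed 1.5-fold, 87.2% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 3.64% of its calls were false. Each simulated gene had the typical spread of its expression level, with no variation between genes around it. Genes with a larger spread are therefore found less often than these rates. In the data Cdkn1a and Gdf15 changed by more than 4-fold and did not pass.

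Then 32 gene lists for cell types and pathways, also fixed beforehand, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Members of each list were counted past the test over all genes and adjusted over the list alone. The genes named were Dnmt1, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 genes per list with the smallest p, and a fixed set of lung genes. As fewer than 10 genes passed as lower, the 10 with the smallest p were named instead and said not to pass. Gene models and identifiers without a symbol were given as counts, some genes that the rule would name are not reported here, and any gene named outside this rule was chosen after its values were seen.

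Alternatives were the replicate number as a block, removal of the 25% of genes with the lowest means, quantile normalization, median centring, moderation without trend or robust estimation, sample weights, removal of erythroid genes, a limit of 1 on the absolute log2 fold change, and leaving out each library. Scaling to the totals of the recovered reads and voom on those reads were added after the data were seen. Alternatives planned for count tables or linear values did not apply.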

Results

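RNA was sequenced from mouse lungs taken at E12.5, in mid-gestation. In 3 libraries, here called Dnmt1KO, the animals carried a deletion of Dnmt1 made by Cre recombinase from the Shh locus, which is active in the endoderm that lines the developing airways. The other 3 libraries, called WT, came from wild-type littermates. Dnmt1 encodes the maintenance methyltransferase that copies DNA methylation onto newly made strands. The labels name the tissue only as lung, with no sorting step, and do not say whether each library came from its own embryo, so the p-values measure the spread between these samples. The comparison asks how expression in the lung depends on Dnmt1, with the title of the series pointing to proximal-distal pattern and to alveolar type 2 cells, which make surfactant.

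The deposited values covered 14162 genes in every library. The read numbers recovered from them came to 18192629, 20126806 and 21046831 in Dnmt1KO replicates 1, 2 and 3 and to 25597662, 20599736 and 23181312 in WT replicates 1, 2 and 3. Across genes, which are not independent replicates, Pearson's r between libraries ran from 0.979 to 0.981 within Dnmt1KO, from 0.975 to 0.987 within WT and from 0.966 to 0.979 between the groups. The first principal component took 42.8% of the variance and placed the Dnmt1KO libraries between -33.6 and -17.5 and the WT libraries between 12.9 and 37.2. Dnmt1KO replicate 1 held 3 reads over Ddx3y, Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, while each of the other 5 libraries held between 4155 and 5207, so sex was not balanced between the groups.

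Dnmt1 itself stood at log2 values of 15.43 ± 0.13 in Dnmt1KO and 15.74 ± 0.02 in WT (SD, n = 3 each), with 8723, 8565 and 8388 reads in the Dnmt1KO libraries against 13466, 10786 and 12602 in the WT libraries before scaling. The Dnmt1KO level was 80.7% of the WT level, a log2 difference of -0.31 ± 0.09 (SE). All 3 Dnmt1KO values lay below all 3 WT values. The difference did not pass limma's test (adjusted p = 0.507), and an exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. A value for the whole gene includes transcripts of cells outside the Cre lineage and exons that the deletion leaves in place.

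The Dnmt1KO lungs expressed a set of germline genes that had few or no reads in WT lungs. Dazl, an RNA-binding protein of germ cells, had 437, 346 and 1055 reads in the Dnmt1KO libraries and 0, 3 and 2 in the WT libraries, a ratio of scaled reads of 425 with an exact 95% counting interval of 182 to 1312 (log2 fold change 8.58 ± 0.78 SE, limma adjusted p = 0.00346). Sohlh2, a transcription factor of early germ cells, had a ratio of 256 (135 to 561, adjusted p = 0.000903). For Tex19.1, which restrains transposons in germ cells, the ratio was 175 (88.3 to 405, adjusted p = 0.000903). Mov10l1, a helicase of the piRNA pathway, had 62, 59 and 160 reads against 5, 0 and 0, a ratio of 65.0 (27.5 to 202, adjusted p = 0.034). The testis tubulins Tuba3b, at 384, 198 and 1114 reads against 1, 0 and 1, and Tuba3a, at 245, 192 and 628 against 4, 5 and 3, also rose, with ratios of 981 (271 to 8110) and 103 (58.6 to 199) and adjusted p of 0.000903 for both. These tubulins are near-identical copies, so how their reads were divided between them is uncertain. These intervals cover counting error only. As each library was left out, the log2 fold change ran from 7.65 to 9.22 for Dazl, from 8.31 to 9.52 for Tuba3b and from 5.86 to 7.52 for Mov10l1.

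Of the 27 measured germline genes on a list of 51, 8 rose, none fell and 19 did not pass the test over all genes, the remaining risers being Rpl10l (adjusted p = 0.0465) and Syce1 (0.0456). Syce1 did not pass without any 1 of the 6 libraries (0.0514 to 0.246), and Rpl10l passed only without WT replicate 1 (0.0801 to 0.313 without any other). With quantile normalization neither passed (0.178 for Rpl10l and 0.132 for Syce1). The count was 5 without any of the 3 Dnmt1KO libraries in turn or without WT replicate 3. Adjusted over the list alone, 19 rose, and 26 of the 27 had a positive fold change. The median log2 fold change of the 27 was 2.66, and 24 of them were among the 25% of genes with the lowest means, without which the median of the 3 left was 0.36 (camera adjusted p = 0.0025). The lowest gene total in the table was 60 reads, so the median does not cover germline genes with few reads in both groups. Against other genes, camera with a preset correlation gave the list an adjusted p of 3.6e-38, which became adjusted p = 0.0658 with an estimated correlation. Fry, which tests the list against no change and not against other genes, gave adjusted p = 0.0172. The same 27 genes had medians of 2.66, 1.86 and 2.97 above the WT mean in Dnmt1KO replicates 1, 2 and 3.

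**Figure D1:**
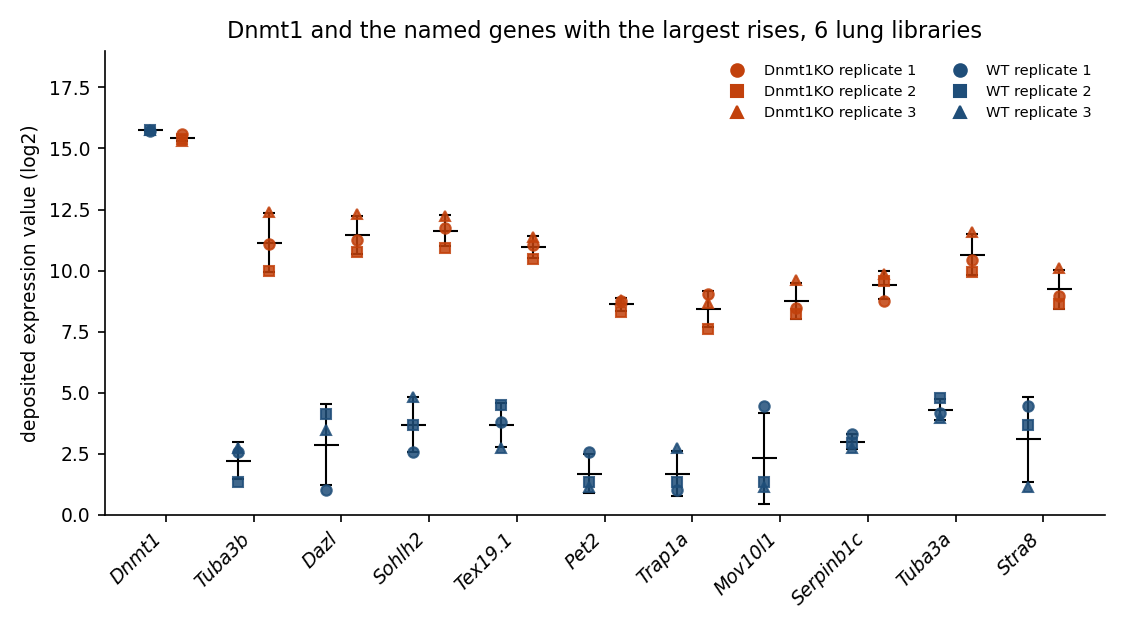
Deposited log2 expression values of Dnmt1 and of the 10 named genes with the largest rises, with Dnmt1KO libraries in orange and WT libraries in blue, a symbol for each replicate, and bars for the mean and SD of 3 libraries. Dnmt1 lies at 15.43 in Dnmt1KO and 15.74 in WT, while Dazl lies at 11.45 in Dnmt1KO and 2.87 in WT, close to the value of a gene without reads.

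Across all genes, limma called 40 higher and 1 lower in Dnmt1KO. Of the 40, 28 had 10 or fewer reads in every WT library and 37 had a fold change above 4. The 12 largest rises included the 6 germline genes above, and 2 of the 12 were gene models without a common name. Among the others, Trap1a, a tumour rejection antigen of the X chromosome, had 93, 38 and 83 reads against 0, 0 and 1, a ratio of 248 (44.0 to 9827, adjusted p = 0.00689). Pet2 had 76, 62 and 91 reads against 1, 0 and 0, a ratio of 265 (47.1 to 10513, adjusted p = 0.00251). Serpinb1c, a serine protease inhibitor, had a ratio of 121 (47.0 to 447, adjusted p = 0.000903), and Stra8, the gene induced by retinoic acid when germ cells enter meiosis, a ratio of 65.3 (31.4 to 163, adjusted p = 0.0312). The log2 fold change of Stra8 ran from 5.17 to 6.83 as each library was left out. The 40 also included genes with clear WT expression, chosen here after their values were seen. Dram1, an autophagy regulator that p53 activates, rose by 2.06 ± 0.25 (adjusted p = 0.0147), Krt23 by 2.68 ± 0.31 (adjusted p = 0.0146), Fermt1, which links integrins to the cytoskeleton in epithelia, by 1.62 ± 0.18 (adjusted p = 0.0107), and Noct by 1.26 ± 0.16 (adjusted p = 0.0176).

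The number of genes called higher was 15 without Dnmt1KO replicate 1, 25 without Dnmt1KO replicate 2 and 25 without WT replicate 3, and it was 0 once the 25% of genes with the lowest means were left out, a step that removed 37 of the 41 called genes and left 308 genes at an unadjusted p under 0.05. The 308 were of 10621 genes tested, below the share of 0.05 given on average where no gene differs. Without Dnmt1KO replicate 1, Mov10l1 (adjusted p = 0.2), Stra8 (0.184), Trap1a (0.102), Dram1 (0.0513), Fermt1 (0.0797) and Noct (0.138) did not pass. Of these, Mov10l1 also failed without any other library except WT replicate 1, Stra8 without Dnmt1KO replicate 2, Dnmt1KO replicate 3 or WT replicate 2, Dram1 without WT replicate 2, Fermt1 without Dnmt1KO replicate 2, and Noct without Dnmt1KO replicate 2, WT replicate 2 or WT replicate 3, as did Krt23 without WT replicate 3 (0.0793). With voom on the recovered reads, Tuba3b (adjusted p = 0.488), Dazl (0.13), Sohlh2 (0.0739), Tuba3a (0.125), Stra8 (0.0739), Krt23 (0.0731) and Syce1 (0.121) did not pass. Without trend and robust estimation, Mov10l1 (0.102), Stra8 (0.102), Syce1 (0.103), Dram1 (0.0836), Noct (0.0836) and Krt23 (0.0569) did not pass. Dram1 and Noct also did not pass once the 25% of genes with the lowest means were left out (0.129 for both).

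Falls were smaller. Ptch1, the receptor and target gene of Hedgehog signalling, was the gene called lower, at 14.41 ± 0.05 in Dnmt1KO against 15.05 ± 0.11 in WT (SD, n = 3), a log2 fold change of -0.63 ± 0.08 (SE, limma adjusted p = 0.0258). The other genes with the smallest p among those with a negative fold change did not pass the test. They were Irx1, a homeobox gene of the lung epithelium (-0.96 ± 0.15, adjusted p = 0.0589), the chloride channel gene Ano1 (-0.76 ± 0.13, 0.0649), the water channel gene Aqp4 (-1.16 ± 0.20, 0.0788), Hhip, a Hedgehog-binding protein that is itself a Hedgehog target (-0.84 ± 0.15, 0.0795), Cdh16 (-1.41 ± 0.25, 0.0795), Rerg (-0.56 ± 0.10, 0.0903), the planar polarity gene Celsr1 (-0.64 ± 0.12, 0.113), Kif12 (-1.53 ± 0.30, 0.13) and 1 gene model. In each of these genes every Dnmt1KO library lay below every WT library, but they were picked by p, so this adds no support. Groups did not overlap in 8.78% of all genes, and chance gives 10%, in either direction. Without Dnmt1KO replicate 3, 17 genes were called lower, with Foxa1 (adjusted p = 0.000667), Irx1 (0.022), Ano1 (0.0314), Cdh16 (0.0391), Kif12 (0.00914) and Celsr1 (0.0393) among them. With sample weights 12 were called lower, among them Irx1, Ano1, Aqp4, Hhip, Cdh16, Rerg and Kif12 (0.014 to 0.0369). There were 3 without WT replicate 1, with Hhip (0.0154) among them, and none without any of the other 4 libraries, where Ptch1 had adjusted p from 0.0822 to 0.174. Ptch1 also did not pass without trend and robust estimation (0.102) or with the lowest 25% of genes removed (0.138).

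Of the 13 measured genes of the Hedgehog list, 1 fell over all genes tested, 6 fell adjusted over the list alone and none rose. They included Ptch1, Hhip, Shh (-0.98 ± 0.22), Gli1 (-0.33 ± 0.07) and Foxf1. The list had a median of -0.15 and a camera adjusted p of 1.95e-07, which became adjusted p = 0.0658 with an estimated correlation. That estimate was -0.032, below the preset 0.01, so correlation between these genes does not account for the change. Fry gave adjusted p = 0.0282 against no change. With sample weights the median was -0.081. Shh, the ligand made by the epithelium, had 361, 608 and 777 reads in Dnmt1KO against 1191, 1273 and 1325 in WT, but did not pass over all genes (adjusted p = 0.213). The labels name Cre for the Dnmt1KO group only. An effect of the Cre allele at the Shh locus therefore cannot be told apart from loss of Dnmt1.

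Of the 21 measured genes of the alveolar type 2 list, 1 rose, 20 did not pass and 6 had a negative fold change. The list median was 0.34 with camera adjusted p = 4.71e-05, against adjusted p = 0.305 with an estimated correlation and adjusted p = 0.117 with fry. With the lowest 25% of genes removed the median of the 13 genes left was 0.21. The gene that rose, Sftpa1, encodes a surfactant protein and went from 9.25 ± 0.28 to 11.16 ± 0.45 (SD, n = 3), a log2 fold change of 1.91 ± 0.24 (SE, limma adjusted p = 0.0193). It did not pass without Dnmt1KO replicate 1 (0.0513), without WT replicate 2 (0.0628), without WT replicate 3 (0.0642), without trend and robust estimation (0.084) or with the lowest 25% of genes removed (0.129). Sftpc, the surfactant gene first seen at the distal tips, stood at 12.43 ± 0.42 against 10.84 ± 0.41 (log2 fold change 1.58 ± 0.25, adjusted p = 0.0585) and did not pass, except with sample weights (0.0454) or without WT replicate 2 (0.0403). Adjusted over the list alone 4 rose, namely Sftpa1, Sftpc, the transcription factor gene Cebpa (0.96 ± 0.22) and the cathepsin gene Ctsh (0.79 ± 0.15). Without Dnmt1KO replicate 3, Cebpa passed over all genes (0.0472).

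Distal tip and general epithelial genes gave a mixed account. On the distal tip list of 17 genes, Id2 (0.56 ± 0.10, limma adjusted p = 0.0879), Clu (0.63 ± 0.13, 0.147) and Sftpc passed adjusted over the list alone but not over all genes. The list was higher by camera (adjusted p = 0.0217, but adjusted p = 0.367 with an estimated correlation). This call ended without Dnmt1KO replicate 1 (0.0787) or WT replicate 3 (0.107), and the median of 0.18 became 0.32 without Dnmt1KO replicate 3 and 0.27 with sample weights. Sox9, the distal tip transcription factor, had a log2 fold change of 0.15 ± 0.24 and Sox2, the proximal one, of -0.39 ± 0.61, both with adjusted p = 1. Sox2 had 90 reads in Dnmt1KO replicate 1 and between 384 and 532 in the other 5 libraries, and without that replicate its difference was 0.35. Of 29 measured lung epithelium genes none passed over all genes, and 5 fell adjusted over the list alone. They were Irx1, Foxa1, a pioneer factor of endoderm (-1.51 ± 0.32), Shh, the splicing regulator gene Esrp2 (-0.53 ± 0.13) and Irx2. The list had a median of -0.091, which ran from -0.24 to 0.045 as each library was left out and was -0.21 with sample weights. The list's camera adjusted p was 0.0209, against adjusted p = 0.83 with an estimated correlation, and the call ended with quantile normalization (0.0533), without Dnmt1KO replicate 2 (0.865), WT replicate 2 (0.542) or WT replicate 3 (0.0518). Nkx2-1, the lung lineage factor (-0.32 ± 0.15), and the epithelial adhesion genes Epcam (0.037 ± 0.18) and Cdh1 (0.17 ± 0.16) did not pass, each with adjusted p = 1. As each library was left out, Nkx2-1 ran from -0.47 to -0.16, Cdh1 from 0.066 to 0.37, Epcam from -0.14 to 0.23 and Sox9 from -0.068 to 0.42. Epcam's sign also turned with sample weights, to -0.14.

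**Figure D2:**
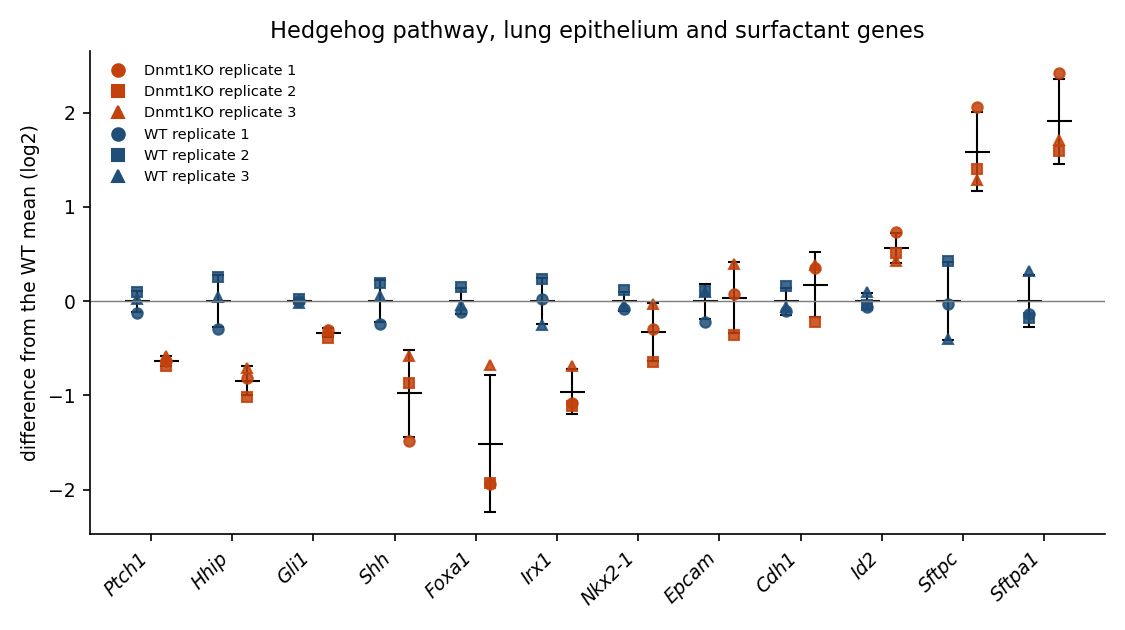
Difference of each library from the WT mean, in log2 units, for 12 genes of Hedgehog signalling, lung epithelium and surfactant, with Dnmt1KO libraries in orange, WT libraries in blue and bars for the mean and SD of 3 libraries. The Dnmt1KO mean lies at -0.63 for Ptch1 and -1.51 for Foxa1, near 0 for Epcam (0.037), and at 1.58 for Sftpc and 1.91 for Sftpa1.

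Of 27 measured genes that p53 activates, none passed the test over all genes, 10 rose adjusted over the list alone and 23 had a positive fold change. The list median was 0.35 with camera adjusted p = 4.48e-12, against adjusted p = 0.353 with an estimated correlation and adjusted p = 0.263 with fry. With the lowest 25% of genes removed the median of the 21 genes left was 0.22. Cdkn1a, the cell cycle inhibitor p21, stood at 11.58 ± 1.11 against 8.88 ± 0.12 (SD, n = 3), with 1021, 761 and 268 reads in Dnmt1KO and 119, 100 and 98 in WT (log2 fold change 2.69 ± 0.49 SE, limma adjusted p = 0.128). Eda2r (2.18 ± 0.37, adjusted p = 0.0764) had the smallest p of the list. After Cdkn1a came the stress cytokine gene Gdf15 (4.76 ± 0.95, adjusted p = 0.141, a ratio of scaled reads of 29.5 with a counting interval of 13.3 to 81.7) and Pmaip1, which promotes apoptosis (2.41 ± 0.53, 0.208). Mdm2, which encodes the ubiquitin ligase of p53, did not pass (0.22 ± 0.09, 0.989). Per library the median lay 0.67, 0.31 and 0.19 above the WT mean in Dnmt1KO replicates 1, 2 and 3. As each library was left out, Cdkn1a ran from 2.24 to 3.31, Gdf15 from 3.83 to 5.39 and Pmaip1 from 1.98 to 3.03. The list median was 0.19 without Dnmt1KO replicate 1 and 0.54 without Dnmt1KO replicate 3. Without Dnmt1KO replicate 3, Cdkn1a (adjusted p = 0.000667), Eda2r (0.00409) and Pmaip1 (0.0159) passed, as these and Gdf15 did with sample weights (0.0134 to 0.0392).

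**Figure D3:**
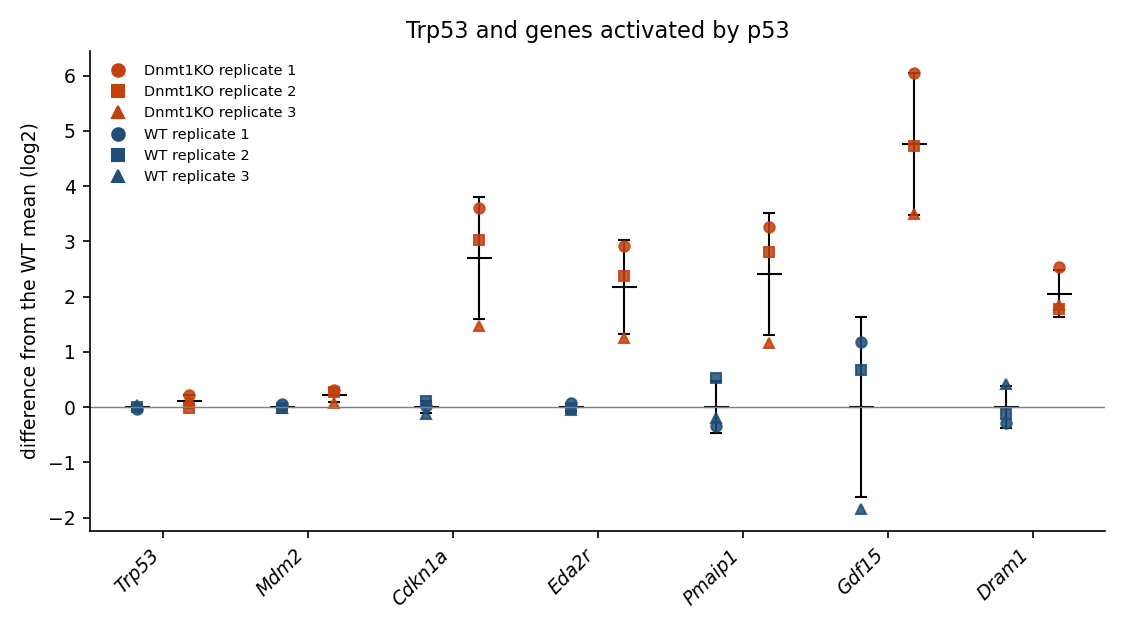
Difference of each library from the WT mean, in log2 units, for Trp53, which encodes p53, and 6 genes that p53 activates, with Dnmt1KO libraries in orange, WT libraries in blue and bars for the mean and SD of 3 libraries. Trp53 lies at 0.11 and Mdm2 at 0.22, while Cdkn1a lies at 2.69, with Dnmt1KO replicate 3 the lowest of the 3 Dnmt1KO libraries.

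Lists of markers of other tissues had calls by camera at the preset correlation only. All 17 measured erythroid genes had a positive fold change, with a median of 0.58, none past the test over all genes or over the list alone (camera adjusted p = 5.25e-08, but adjusted p = 0.419 with an estimated correlation). The median was 0.26 without Dnmt1KO replicate 3 and 0.27 with sample weights. Its per-library median was 1.05 in Dnmt1KO replicate 3, 0.38 and 0.19 in Dnmt1KO replicates 1 and 2, and 0.37 in WT replicate 3. The list of other endoderm organs had 10 measured genes, of which 4 liver genes rose adjusted over the list alone and none over all genes. They were Afp (2.14 ± 0.38, limma adjusted p = 0.0879), Apob (2.83 ± 0.71, 0.336, with a ratio of scaled reads of 9.40 and a counting interval of 4.50 to 22.7), Apoa1 (1.69 ± 0.44, 0.391) and Alb (3.18 ± 0.99, 0.625), with camera adjusted p = 2.08e-05 for the list, against adjusted p = 0.324 with an estimated correlation. The list median of 0.35 became 0.71 without Dnmt1KO replicate 3 and 0.63 with sample weights, and Afp passed with sample weights (0.0401). Apob was at 3.53 without Dnmt1KO replicate 3 and 1.44 with quantile normalization, and Alb ran from 2.48 to 4.12 as each library was left out. The oesophagus and heart list (camera adjusted p = 0.0152, but adjusted p = 0.804 with an estimated correlation) stood at 2.82 above the WT mean in Dnmt1KO replicate 2, where Myh6 of heart muscle had 2293 reads against 40 to 283 in the other libraries. The log2 fold change of Myh6 was 0.95 without that library and 3.69 without Dnmt1KO replicate 1. Its median of 0.85 became 0.13 without Dnmt1KO replicate 2, 1.78 without Dnmt1KO replicate 1 and 1.45 with sample weights. Its call ended without Dnmt1KO replicate 2 (0.432), without Dnmt1KO replicate 3 (0.105) or without WT replicate 3 (0.19).

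The interferon list was higher, with 17 of 21 genes positive and 2, H2-K1 (0.88 ± 0.19) and Bst2 (0.65 ± 0.17), past the test adjusted over the list alone but none over all genes (camera adjusted p = 0.000142, but adjusted p = 0.416 with an estimated correlation). The WNT list of 23 genes was lower, with a median of -0.14 and none past either adjustment (camera adjusted p = 0.0025, but adjusted p = 0.332 with an estimated correlation). Without WT replicate 1 its adjusted p was 0.0817. The cell cycle list of 28 genes was lower, with a median of -0.042 (camera adjusted p = 0.0349, but adjusted p = 0.83 with an estimated correlation), and the 12 multiciliated genes were higher by a median of 0.17 (adjusted p = 0.0101, but adjusted p = 0.332 with an estimated correlation), a median that turned to -0.023 with quantile normalization (adjusted p = 0.498). Neither had a member past either adjustment. The cell cycle median turned to 0.021 without Dnmt1KO replicate 2 and to 0.0010 without WT replicate 3, and was -0.11 with sample weights. The cell cycle call ended without Dnmt1KO replicate 2 (0.696), WT replicate 2 (0.519) or WT replicate 3 (0.402), with quantile normalization (0.41) and with the lowest 25% of genes removed (0.112). The multiciliated call ended without Dnmt1KO replicate 3 (0.0512) or WT replicate 3 (0.0907) and with the lowest 25% of genes removed (median 0.042, adjusted p = 0.385), and its median ran from 0.11 to 0.27 as each library was left out. The 4 measured sex chromosome markers were lower by camera (adjusted p = 0.0462, but adjusted p = 0.804 with an estimated correlation), and the call ended without Dnmt1KO replicate 1 (0.232) or any WT library (0.0899 to 0.12), with quantile normalization (0.0856) and with sample weights (0.121). The interferon median of 0.22 was 0.35 without Dnmt1KO replicate 2, 0.12 with quantile normalization, 0.099 with sample weights and 0.067 over the 8 genes left with the lowest 25% removed.

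In all, camera with a preset correlation called 9 lists higher and 5 lower of 32, none with an estimated correlation, while fry, which asks whether a list's genes move one way on balance, called the germline and Hedgehog lists. The estimated correlation was -0.032 for the Hedgehog list and 0.63 for the erythroid list. A call lost with the estimate therefore does not by itself show correlated genes. Without WT replicate 3 camera at the preset correlation called 9 lists in all. The other 18 lists did not pass camera, with adjusted p from 0.132 to 0.991. They were DNA methylation machinery, proximal airway epithelium, neuroendocrine cells, alveolar type 1 cells, mesenchyme, smooth muscle, cartilage, endothelium, leukocytes, mesothelium, neural and neural crest cells, imprinted genes, clustered protocadherins, FGF signalling, BMP and TGF-beta signalling, retinoic acid and NOTCH signalling, immediate early and stress genes, and hypoxia and glycolysis. With 1 library left out, camera at the preset correlation called, in at least 1 such fit, DNA methylation machinery, neuroendocrine, alveolar type 1, smooth muscle, cartilage, endothelium, mesothelium, neural, protocadherin, retinoic acid and NOTCH, and hypoxia lists. Among their members and those of the multiciliated list, Foxj1 of multiciliated cells (0.10 ± 0.28, turning to -0.20 with quantile normalization), Trp63 of basal cells (2.08 ± 0.67, or 1.40 to 2.51 as each library was left out) and Hopx of alveolar type 1 cells (0.93 ± 0.33) did not pass. Of 33 measured imprinted genes none passed over all genes or over the list alone.

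**Figure D4:**
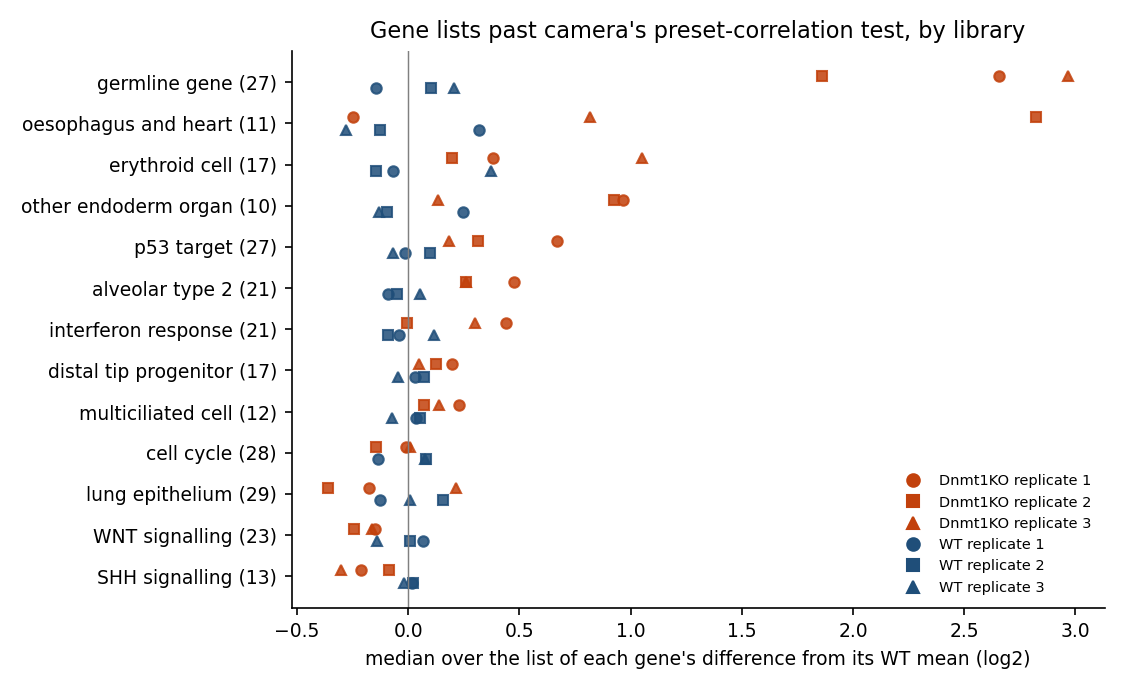
Median, over each of the 13 lists past camera's test with a preset correlation other than the sex chromosome markers, of the differences of its genes from their WT means in each library, in log2 units, with Dnmt1KO libraries in orange, WT libraries in blue and the number of measured genes in parentheses. The germline list lies at 1.86 to 2.97 in the Dnmt1KO libraries, and the Hedgehog list at -0.30 to -0.085.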

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

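The scaling to recovered library totals and voom on the recovered reads were chosen after the data were seen. The groups did not overlap in any called gene, so leaving out a library could not turn its sign. A change of block, moderation, fold-change limit or genes tested could not do so either. Every called gene that was tested kept its direction in all 16 alternatives to the fit, 41 of 41 in 15 of them and 4 of 4 with the 25% of genes with the lowest means removed. That removal left 0 genes called higher, 0 lower and 0 germline genes, with a germline list median of 0.36 over the 3 members left (308 genes at an unadjusted p under 0.05, against 640 in the full fit), because 37 of the 41 were no longer tested and the adjustment of the other 4 no longer drew on the small p-values of those genes. Where no gene differs, a share of 0.05 of the genes tested has such a p on average. The 308 of 10621 and the 640 of 14162 lay below that share, so these counts alone show no difference. The replicate block gave 26 higher and 0 lower (771 of 14162 genes at an unadjusted p under 0.05, slightly above that share), with 23 genes shared with the 41. Among those not called with it were Ptch1 (adjusted p = 0.0532), Sftpa1 (0.0594), Mov10l1 (0.0839), Syce1 (0.0899), Rpl10l (0.0993), Stra8 (0.138) and Dram1 (0.138), while Gdf15 was called (0.0493). Same-numbered samples' deviations from their group means correlated at -0.0027, -0.18 and 0.31, and not every sample correlated best with its own number, so the numbers were not used as pairs. Genes called lower numbered 0 without trend and robust estimation (706 at an unadjusted p under 0.05), 0 with a limit of 1 on the absolute log2 fold change and 12 with sample weights, where 57 were higher. Quantile normalization gave 29 higher and 1 lower, and the added voom fit 31 and 1, with 4 germline genes. Of 14 lists called by camera, 0 passed with an estimated correlation and 2 with fry. Leaving out each library gave 15 to 42 genes higher, 0 to 17 lower, 5 to 8 germline genes and 9 to 16 lists. In those fits 517 to 811 of 14162 genes had an unadjusted p under 0.05, on either side of a share of 0.05. Dnmt1 lay between -0.38 and -0.25 there and did not pass in any fit. Signs turned in genes that had not passed and in medians of lists. Epcam was at -0.14 with sample weights and Foxj1 at -0.20 with quantile normalization, where the multiciliated median was -0.023. Over the fits without a library, Sox2 ran from -0.82 to 0.35, Sox9 from -0.068 to 0.42, Epcam from -0.14 to 0.23 and Foxj1 from -0.029 to 0.19. The list medians ran from -0.24 to 0.045 for lung epithelium, -0.12 to 0.021 for the cell cycle, -0.12 to 0.12 for endothelium, -0.60 to 0.64 for neural and neural crest cells, -0.17 to 0.14 for retinoic acid and NOTCH, and -4.72 to 0.11 for sex chromosome markers, the last through the loss of the library without Y reads. For the other changes the cause was not tested. Depth limits the genes with few WT reads, whose ratios have wide counting intervals.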

Other observations

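The tests of explanations in this part were set out after the values had been seen, although the count over other splits of the samples was planned beforehand. The genes in this paragraph were chosen after their values were seen. Lcn2 had 0, 3 and 1 reads in Dnmt1KO against 37, 24 and 14 in WT, a ratio of scaled reads of 0.0617 with a counting interval of 0.0164 to 0.165 (limma adjusted p = 0.173). Its log2 fold change ran from -4.56 to -3.22 as each library was left out. Ltf had 9, 10 and 3 reads against 61, 56 and 22 (log2 fold change -2.40 ± 0.61 SE, adjusted p = 0.348), or -3.84 with quantile normalization. Neither passed the test. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, had log2 fold changes of 0.83 ± 0.19 and 1.88 ± 0.29 (adjusted p = 0.212 and 0.0521), which did not pass. Mt2 passed without WT replicate 2 (0.0258), with sample weights (0.0188) and with scaling to the recovered library totals (0.046). The Iroquois homeobox genes Irx3 and Irx5 and the transcription factor gene Tbx1 had log2 fold changes of -0.76, -0.60 and -1.32 with all libraries, which did not pass (adjusted p = 0.691, 0.886 and 0.208). They were called lower without Dnmt1KO replicate 3, at -1.04, -0.88 and -1.67 (adjusted p = 0.048, 0.0391 and 0.00956).

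Genes called higher were more often X-linked than other genes. By identifier in the GRCm38 annotation, 11 of the 38 called genes with a known chromosome lay on the X chromosome (28.9%), against 494 of 13967 tested genes (3.54%), an odds ratio of 11.3 with a 95% interval of 5.04 to 23.8 (two-sided Fisher's exact test, p = 4.91e-08). None of the 11 was on the germline list, but that list holds other Rhox and Xlr genes. The X-linked share is therefore not shown to be separate from the germline rise. The 11 included Trap1a, Pet2, Tex13b, Rhox2a, Rhox4a and Xlr3c. The Rhox and Xlr genes belong to families of similar copies, so the genes are not independent and some may share reads. With a library left out, Rhox4a passed only without WT replicate 1 or WT replicate 2, and Xlr3c only without WT replicate 1, while Trap1a and Rhox2a did not pass without Dnmt1KO replicate 1 (adjusted p = 0.102 and 0.125). With quantile normalization Rhox4a (0.176) and Xlr3c (0.0676) did not pass, nor did Xlr3c with voom on the recovered reads (0.0942) or without trend and robust estimation (0.0961). Without Dnmt1KO replicate 1, the library without Y reads, 4 of 15 called genes were X-linked (two-sided Fisher's exact test, p = 0.00155).

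The order of the Dnmt1KO libraries differed between lists. In Dnmt1KO replicates 1, 2 and 3, medians above the WT mean were 2.66, 1.86 and 2.97 for the germline list, 0.67, 0.31 and 0.19 for p53 targets and 0.48, 0.26 and 0.26 for alveolar type 2 genes. The Hedgehog list lay at -0.21, -0.085 and -0.30, and the erythroid list at 0.38, 0.19 and 1.05. Foxa1 had 318, 355 and 884 reads, against 1576, 1498 and 1513 in WT. With 3 libraries no relation between these measures was tested.

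For the germline genes, the tables argue against both technical explanations weighed, the first within a limit. Germ cells carried into the knockout samples would bring other markers of primordial germ cells. Of such markers outside the germline list, 10 had fewer WT reads than Dazl's mean of 613 in Dnmt1KO, and all have reads in WT lungs too. Their median log2 fold change was 0.072 and their range -1.17 to 0.27, with Dnd1 at -0.11 and Nanos3 at 0.12. Their WT means ran from 21.3 reads for Tfap2c to 456 for Ifitm3. Germ cells that add far fewer reads of these markers than of Dazl are therefore not excluded. Dnmt1KO replicate 1 alone does not account for the germline rise. The list medians of replicates 2 and 3 lay 1.86 and 2.97 above the WT mean and those of the WT libraries between -0.14 and 0.20. Without replicate 1 only 5 of the list's genes were called, and the list had adjusted p = 0.171 by camera with an estimated correlation and 0.073 by fry. A candidate explanation is that loss of Dnmt1 in the endoderm releases genes normally held silent by DNA methylation, which stays a hypothesis because no methylation was measured here.

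For the alveolar type 2 genes, neither technical explanation weighed was excluded. A larger share of epithelium in the sample would raise general epithelial genes as well, and the lung epithelium list had a median of -0.091. The SD of 0.45 over its members is a spread between genes. In Dnmt1KO replicates 1 and 2 that list lay at -0.18 and -0.36, below every WT library, and the alveolar type 2 list at 0.48 and 0.26. The WT libraries ran from -0.13 to 0.16, so replicate 1 lay only slightly below them. The list also holds Foxa1, Irx1, Irx2, Shh and Esrp2, which fell adjusted over the list alone, so it is not a neutral measure of share. These values give no sign of a larger share in those libraries but do not exclude it. In Dnmt1KO replicate 3 the lists lay at 0.21 and 0.26, so a larger share stays open there as well. Whether the knockout embryos were at a later stage than their littermates also stays open, with the alveolar type 1 list at a median of 0.096 and an SD between its genes of 0.28. As each library was left out that median ran from 0.00031 to 0.17, and camera at the preset correlation called it higher without WT replicate 2 (adjusted p = 0.0107) and without Dnmt1KO replicate 2 (0.0419). A shift of epithelial cells towards the alveolar type 2 program may also account for it and was not tested apart from share or stage.

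For the p53 target genes, neither technical explanation weighed was excluded. In 14 of the 27 genes every Dnmt1KO library, replicates 2 and 3 included, lay above every WT library. Groups did not overlap in 8.78% of all genes, in either direction. The 14 were picked by this lack of overlap, so in them replicates 2 and 3 lie above WT by choice. The genes of the list are also correlated (estimated correlation 0.42), and their share without overlap was not tested. Whether Dnmt1KO replicate 1 alone is the source stays open, as the list medians of replicates 2 and 3 were 0.31 and 0.19 and the highest WT library was at 0.097. Without replicate 1 the list had adjusted p = 4.69e-08 by camera at the preset correlation. It had adjusted p = 0.401 by camera with an estimated correlation and 0.388 by fry. Neither of these had passed with all libraries (0.353 and 0.263). Cdkn1a still had 761 and 268 reads in replicates 2 and 3 against 98 to 119 in WT. Stress from handling of the knockout samples was not settled either. The immediate early and stress list had a median of 0.016, with 11 genes positive and 11 negative, and so showed no general rise. Its SD of 0.32 is a spread between genes and not the error of that median. In 4 of its 22 genes every Dnmt1KO library lay above every WT library, and in 0 below, so a rise of some members stays open. Fos (1.17 ± 0.35, limma adjusted p = 0.585) and Jun (-0.38 ± 0.14, adjusted p = 0.857) had opposite signs without passing. Trp53 itself differed by 0.11 ± 0.08 (0.053 to 0.17 as each library was left out), so a candidate explanation is p53 activity raised without more of its transcript, for which protein was not measured.

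The real split of the 6 samples called 41 genes, and the highest of the other splits called 4. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.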
